A study of Arabidopsis thaliana with 18 samples.

How the data were processed

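The study measured total RNA from Arabidopsis thaliana roots on 18 Affymetrix gene arrays, 3 in each of 6 groups: root MS, root DEX, root CHX and root DEX+CHX (whole root tips, Col-0, 1 h) and J0571 control and J0571 DEX (sorted GFP-positive cells, C24, 2 h). Per the labels' protocols, RNA was reverse transcribed as whole-transcript cDNA and labelled with biotin, and sorted cells came from protoplasted roots. The deposited values are log2 signals made with RMA by the authors, per the submitters' processing notes. RMA includes background correction, quantile normalization and a summary over probes. Its version, and whether all 18 arrays were normalized together, are not given in the sources used here. From the values, 1401 exact numbers recur between the root and the J0571 arrays, no 2 arrays are identical, and the SD between the arrays' values at equal rank is at most 0.16 log2. For arrays, their number limits the precision, and low signals lie close to background.

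The table has 38408 features. The platform's table of probes and genes names 17481 of them, 16722 for exactly 1 gene and 759 for several; the other 20927 are called unnamed here, which does not mean that they lie in no gene. Gene symbols and locus IDs were updated by their Entrez identifiers through the reference annotation TAIR10.1, which linked 16574 of the 16722 to a locus, 16548 loci in all, 148 of them with more than 1 feature. No gene is named from a feature with several genes. Control features could not be told from others, so all 38408 were tested. Of the features, 7132 (18.6%) share their values on every array with at least 1 other feature, in sets of up to 29 copies, so that 32879 are distinct; 6976 of the repeated ones are unnamed here.

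Differences were tested with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8) on the deposited log2 values as given: a linear model with 1 mean per group, moderated variances (eBayes), a two-sided moderated test per feature and Benjamini-Hochberg adjustment over all features, with adjusted p under 0.05 as the threshold. The 4 root groups were fitted together, the J0571 groups separately, and the comparisons between experiments over all 18 arrays. The median residual SD was 0.190 in the root fit and 0.204 in the J0571 fit. Contrasts were root DEX against root MS, root DEX+CHX against root CHX, root CHX against root MS, the interaction of DEX and CHX, J0571 DEX against J0571 control, the difference between the J0571 response and each root DEX response, and J0571 control against root MS. The p-values measure the spread between samples labelled as repeats; no label says whether these were separate cultures or treatments. Changes are log2 with limma's SE; levels are means with SD over 3 arrays.

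Before the data were examined the comparisons, 23 gene lists, the alternatives and the rule for named genes were fixed. That rule names, per DEX or CHX contrast, the 12 largest increases and 8 largest decreases among called features of exactly 1 gene whose groups do not overlap, or the 5 of smallest p where fewer than 5 pass; for the interaction, the 5 of smallest p each way; LHW in every contrast (TMO5 and LOG4 were in the rule but are unnamed here); and list members past the threshold. A gene with several features is represented by that of highest mean. Other genes in the text passed in a test of a difference, complete a list or were chosen after their values were seen, as stated. Of the 239 loci in the lists, 30 have a feature named here for exactly 1 gene, so the lists are thinly covered. Tested as lists were the 8 with at least 2 such members: the TMO5 and LHW family (3 of 8), SAC51 family (2 of 4), type-A response regulators (2 of 10), early auxin response (8 of 19), polyamine synthesis (3 of 10), vascular Dof factors (2 of 7), ground tissue markers (4 of 17) and epidermis and root hair markers (2 of 8). Another 5 lists had 1 member, given as a gene: reported TMO5-LHW targets (DOF2.1), procambium and xylem (PHV), phloem (OPS), early stress response (STZ) and shoot photosynthesis (RCA). The remaining 10, among them cytokinin biosynthesis, degradation and perception, auxin transport, cell cycle and stele, had no named member and were not analysed here. Genes of some lists stand in more than 1 list.

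Lists were tested with limma's camera with the preset correlation of 0.01 and again with an estimated correlation, 1 feature per gene over all named genes, adjusted over the 8 lists of a contrast. Calls within a list are also given adjusted over the list alone. Overlaps of the DEX contrasts, which share no arrays, were tested with a one-sided hypergeometric test. The procedure was tested on simulated data with the means and moderated spreads of all 38408 features. Of these, 200 were changed by known folds. There 2-fold changes were recovered in 73.1% of cases for root DEX, 59.7% for root DEX+CHX against root CHX, 67.2% for root CHX and 35.8% for J0571 DEX. For 4-fold changes the shares were 98.5%, 91.0%, 94.0% and 94.0%. The root contrasts were simulated from the same means and spreads, so the differences between their shares reflect only which features and noise were drawn. Each share of 2-fold changes rests on 67 features. Noise was drawn independently for each feature, also for those that are identical in the data. These shares hold for 200 changed features. Where fewer features change, the adjusted p of a given change can be larger. A count of 0 therefore does not show that 2-fold changes are absent.

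The alternatives tried were quantile normalization of the arrays, equal array medians, leaving out the 30% of features with the lowest mean, eBayes with trend and robust options, array weights, a replicate block, a 1.5-fold minimum, fits over all 18 arrays or over only the 6 arrays compared, leaving out each array in turn, and for the overlap the 200 features of smallest p. Chosen after seeing the data were counting identical features once, testing only features of 1 named gene, leaving out arrays for 2 of the lists, families of genes that share a symbol stem, and the overlaps in other pairs of directions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.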

Results

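Transcript levels were measured on 18 arrays, in 6 groups of 3, from roots of Arabidopsis seedlings 4 days old. TMO5 is a basic helix-loop-helix (bHLH) transcription factor that pairs with LONESOME HIGHWAY (LHW) in vascular development. TMO5-GR is its fusion to the glucocorticoid receptor, which acts once dexamethasone (DEX) is present. Root tips of a Col-0 line with pRPS5A-TMO5-GR, a construct active in dividing cells, were collected after 1 h on medium alone (root MS), with DEX (root DEX), with cycloheximide, an inhibitor of protein synthesis (root CHX), or with both (root DEX+CHX). In the other experiment J0571, a GAL4 enhancer trap line known to be active in ground tissue, drove TMO5-GR in the C24 background. Its GFP-positive cells were sorted from protoplasted roots 2 h after transfer to medium alone (J0571 control) or to DEX (J0571 DEX). TMO5 itself and its reported target LOG4 could not be followed, because neither is among the 16722 features named here for exactly 1 gene.

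Within groups, pairs of arrays correlated with r from 0.982 to 0.992 across features, which are not independent replicates. The median log2 signal per array was 4.76 to 4.85 in root MS, 4.82 to 4.87 in root DEX, 4.62 to 4.63 in root CHX, 4.61 to 4.65 in root DEX+CHX and 4.50 to 4.58 in the J0571 arrays. The first principal component of the root arrays held 70.1% of the variance and parted the CHX groups (56.5 to 69.3) from the groups without CHX (-64.7 to -58.7). Among the J0571 arrays that component held 33.0%, and J0571 control replicate 3 lay at 49.2, apart from the other arrays (-29.9 to 7.23).

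The comparison of sorted J0571 cells with and without DEX asks which transcripts changed in ground tissue 2 h after DEX was given to a line carrying TMO5-GR. AT4G38650, annotated as a glycosyl hydrolase of family 10, rose from 5.30 ± 0.20 to 8.56 ± 0.15 (log2 signal, mean ± SD, n = 3 per group), a log2 change of 3.26 (SE 0.15, adjusted p = 0.00267). AT1G28160, a transcription factor of the ERF/AP2 class, rose by 2.35 (SE 0.20, adjusted p = 0.0384) from 5.50 ± 0.32 to 7.85 ± 0.22. AT2G34655 fell by 1.63 (SE 0.12, adjusted p = 0.0237) from 5.68 ± 0.14 to 4.05 ± 0.11. For each of these 3 genes the arrays of one group lay entirely above those of the other. The next named genes did not pass: IQD18, of the calmodulin-binding IQ-domain family, had a log2 change of 1.15 (SE 0.12, adjusted p = 0.111), and TET5, a tetraspanin, -1.09 (SE 0.13, adjusted p = 0.163).

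Over all features, 13 passed in J0571 cells, 12 risen and 1 fallen, or 10 when features with identical values are counted once; 2239 had an unadjusted p under 0.05. Among the unnamed features that rose were 13545421, by 4.15 (SE 0.20), and 13433216, by 2.48 (SE 0.11). The fit over all 18 arrays called 68, 49 risen and 19 fallen, among them IQD18 (adjusted p = 0.000321, and 0.0115 with the trend and robust options) and TET5 (adjusted p = 0.000719). The count was 5 without J0571 control replicate 2, J0571 DEX replicate 1, J0571 DEX replicate 2 or J0571 DEX replicate 3, and 8 without J0571 control replicate 3. AT4G38650 passed in each of the 6 fits that left out 1 array. It did not pass with the replicate block (adjusted p = 0.137), which gave 0 calls. The calls of AT1G28160 (adjusted p from 0.0772 to 0.303) and AT2G34655 (0.0762 to 0.246) were lost in all 6, whichever array was left out, and that of AT1G28160 also with quantile normalization (0.0577).

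**Figure D1:**
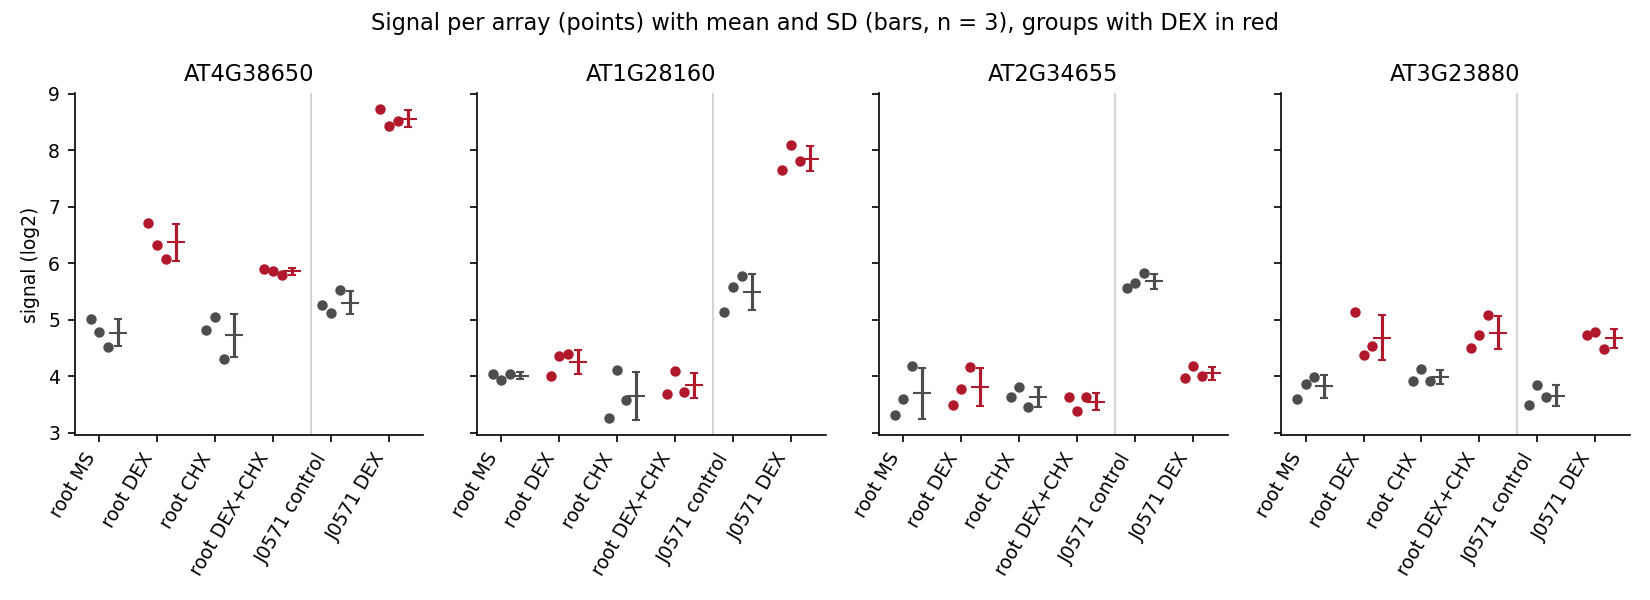
Signal (log2) of AT4G38650, AT1G28160, AT2G34655 and AT3G23880 on each of the 18 arrays, by group, with mean and SD (n = 3); groups with DEX are red, and the line parts the root arrays from the J0571 arrays. AT4G38650 lay between 8.44 and 8.73 in J0571 DEX and between 5.12 and 5.52 in J0571 control, while AT1G28160 and AT2G34655 differed by at most 0.25 between root groups with and without DEX.

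No member of any gene list passed over all features in J0571 cells, and limma's camera found lower values for 2 lists. The 8 early auxin response members named here, of 19 in the list, all had log2 changes below 0 (median -0.25), among them WES1 (GH3.5) at -0.69 (SE 0.19) and LBD16 at -0.67 (SE 0.21). Their adjusted p was 0.00947, and 0.228 with an estimated correlation. The TMO5 and LHW family (3 of 8 named) had a median of -0.29 (adjusted p = 0.0135, and 0.383 with an estimated correlation), with AT2G41130 at -0.46 (SE 0.15) and LHW at -0.29 (SE 0.10); both fell when adjusted over the list alone. Adjusted p for the other 6 lists ran from 0.939 to 0.959. The ground tissue markers had a median of 0.03, a mean of -0.08 and a test pointing down.

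In root tips DEX was given for 1 h, alone or with CHX, and the comparison of both asks which responses to DEX occur in this line while protein synthesis is inhibited. AT4G38650 was the named gene of smallest p with DEX alone, at 6.37 ± 0.32 against 4.77 ± 0.24 (log2 change 1.60, SE 0.21). Each root DEX array lay above each root MS array, but the adjusted p was 0.361. Other named genes of small p, none of which passed, were PID2, a kinase related to PINOID, at 0.66 (SE 0.13), AT3G25940 at 0.59 (SE 0.11), AT4G29070 at 0.55 (SE 0.09) and AT1G27270 at -0.61 (SE 0.11). The SAC51 family of bHLH factors, known from the response to thermospermine, was the only list to pass among the 8 tested. Its members named here (2 of 4) were AT5G50010 (SACL2) at 0.54 (SE 0.12) and AT5G09460 (SACL1) at 0.40 (SE 0.15), with an adjusted p of 0.000269 for the list. Both passed when adjusted over the list alone and neither over all features.

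With limma, 0 features passed for DEX alone, 2368 had an unadjusted p under 0.05, and the smallest adjusted p was 0.361. The SAC51 result also passed with an estimated correlation (adjusted p = 0.0250), but not without root MS replicate 1 (0.101), root MS replicate 2 (0.0543) or root DEX replicate 2 (0.0794). Without root DEX replicate 1, 15 features passed, all higher with DEX and all unnamed here, and they held 3 sets of identical values. The fit over all 18 arrays called AT4G38650 alone (adjusted p = 0.0324). Early auxin response members had a median of -0.17 (adjusted p = 0.162) and passed only without root DEX replicate 3 (adjusted p = 0.0202, and 0.0919 with an estimated correlation; up to 0.609 without another array). The remaining 6 lists had adjusted p from 0.366 to 0.920. LHW stood at -0.04 (SE 0.10), and DOF2.1 (AT2G28510), the only reported TMO5-LHW target named here, at 0.11 (SE 0.14). That list holds LOG4, which the study took up on these samples, so it is not independent evidence.

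With CHX present in both groups, AT4G38650 was again higher with DEX, at 5.86 ± 0.06 against 4.73 ± 0.38 (log2 change 1.13, SE 0.21), and did not pass (adjusted p = 1.00). Next by p came AT1G42980 at 0.53 (SE 0.11), AT3G45050 at 0.47 (SE 0.10), AT3G04760 at 0.43 (SE 0.08) and AT1G19550 at -0.50 (SE 0.10). The early auxin response list rose: all 8 members had changes above 0, from 0.13 to 0.87, with a median of 0.23 (adjusted p = 1.23e-05, and 0.00871 with an estimated correlation). IAA29, a repressor of auxin-regulated transcription, was at 0.87 (SE 0.19) and was the 1 member past the threshold when adjusted over the list alone; GH3.3, an enzyme that conjugates auxin to amino acids, was at 0.47 (SE 0.34) and IAA20 at 0.32 (SE 0.16). The SAC51 family also rose (median 0.35, adjusted p = 0.00129, and 0.0273 with an estimated correlation), with AT5G50010 at 0.50 (SE 0.12), past the threshold over the list alone, and AT5G09460 at 0.20 (SE 0.15).

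For this contrast limma called 0 features, with 1189 at an unadjusted p under 0.05. The SAC51 result was lost with an estimated correlation without root CHX replicate 1 (0.0639), root CHX replicate 2 (0.0953) or root DEX+CHX replicate 1 (0.164, and 0.0517 with the preset correlation). Adjusted p for the other 6 lists ran from 0.675 to 0.769. The TMO5 and LHW family had a median of -0.05, a mean of 0.02 and a test pointing down, and the polyamine list a median of -0.01, a mean of 0.11 and a test pointing up. The interaction of DEX and CHX tests whether the response to DEX differed with CHX. It gave 0 calls in limma, with 1684 features at an unadjusted p under 0.05 and a smallest adjusted p of 0.644. By p the leading genes were AT1G27270 at 0.97 (SE 0.16) and CML43, a calmodulin-like protein, at 0.74 (SE 0.13), then AT3G61870 (0.74), AT2G47340 (0.70) and AT3G45050 (0.63). In the other direction they were AT1G19550 at -0.65 (SE 0.13), AT5G17440 (-0.51), AT3G04855 (-1.05), AT5G38750 (-0.62) and AT4G29070 (-0.53). The early auxin response list passed this test of the difference, with all 8 members above 0 (median 0.49, adjusted p = 1.21e-05, and 0.00867 with an estimated correlation). LBD16 at 0.55 (SE 0.15) passed over the list alone. The other lists had adjusted p of 0.839 to 0.852.

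**Figure D2:**
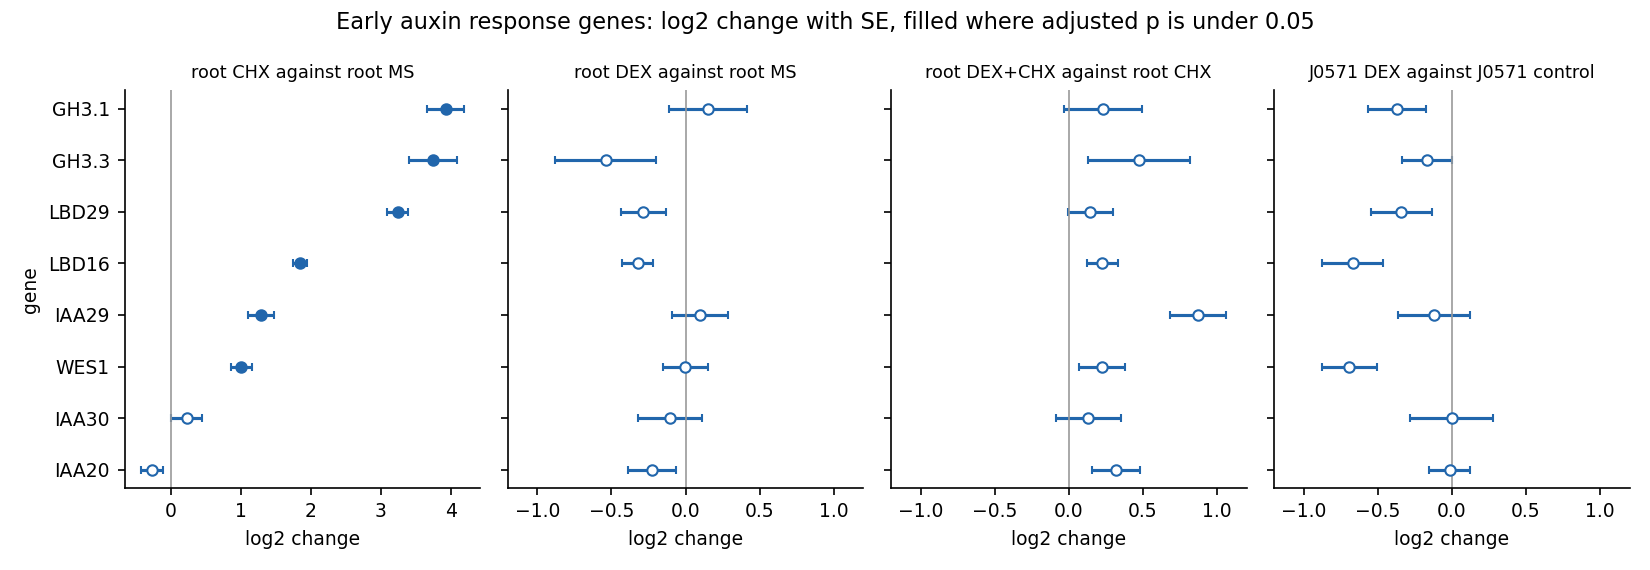
Log2 change (x axis, with SE) of the 8 named early auxin response genes in 4 contrasts, filled where the adjusted p over all features is under 0.05; the panel for CHX has a wider axis. With CHX 6 of the 8 rose, while with DEX all 8 lay above 0 in the presence of CHX (0.13 to 0.87) and all 8 below 0 in J0571 cells.

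Features that led the DEX contrasts were compared between them, since these 3 contrasts share no arrays. Both root contrasts come from the same fit, however, and share each feature's SE. Their rankings by p are therefore not independent, which the test of overlap does not allow for. The 3 contrasts shared no called feature, as both root contrasts had 0 calls. Among the 200 features higher with DEX of smallest p, root DEX and root DEX+CHX shared 12 (1.04 expected for independent lists, one-sided Fisher exact p = 7.41e-10), root DEX and J0571 DEX 8 (p = 1.1e-05), and root DEX+CHX and J0571 DEX 7 (p = 9.15e-05). With identical features counted once, an alternative chosen after seeing the data, the pairs shared 20, 11 and 8, with 1.22 expected. With each contrast then fitted on only its own 6 arrays, they shared 15, 12 and 9. In 5 features all 3 contrasts met, and the 2 named ones were AT4G38650 and AT3G23880, an F-box protein with log2 changes of 0.86 (SE 0.21), 0.78 (SE 0.21) and 1.01 (SE 0.14), of which none passed on its own (adjusted p = 0.426, 1.00 and 0.332). Named genes shared by root DEX and root DEX+CHX included PID2 (0.66 and 0.42), AT5G50010 (0.54 and 0.50) and AT5G39080 (0.95 and 0.66). Those shared by root DEX and J0571 DEX included IQD18 (0.58 and 1.15) and SCPL45, a carboxypeptidase-like protein (0.51 and 0.67). These genes were chosen after their values were seen. Across all distinct features the changes correlated little (Pearson r = 0.0254, 0.0548 and -0.0199 for the same pairs), and features are not independent replicates.

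**Figure D3:**
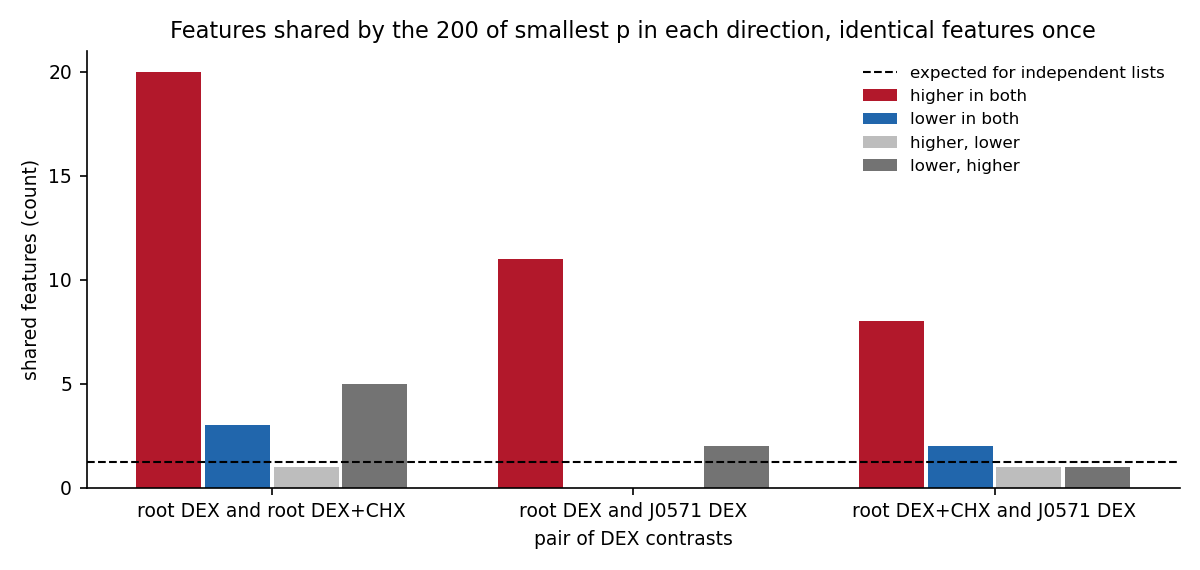
Number of features shared by the 200 of smallest p (y axis) in each pair of DEX contrasts (x axis), identical features once, for features higher in both, lower in both, or in opposite directions; the dashed line is the count expected for independent lists (1.22). Features higher in both numbered 20, 11 and 8, and no other pair of directions exceeded 5.

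Responses to DEX in J0571 cells and in root tips were also compared by the difference of the changes; background, construct, time, protoplasting and sorting all differ between them. The change of AT1G28160 was higher in J0571 cells, by 2.1 over root DEX (SE 0.30, adjusted p = 0.0144), and that of AT2G38380, a class III peroxidase, lower, by -1.27 (SE 0.17, adjusted p = 0.00983). A lower change need not be a weaker response: AT2G34655 changed by -1.63 with DEX in J0571 cells and by 0.11 in root tips. AT3G17130 (1.70, SE 0.27, adjusted p = 0.0300) and AT1G23205 (1.19, SE 0.18, adjusted p = 0.0258), both of the invertase and pectin methylesterase inhibitor class, were likewise higher in J0571, and AT2G34655 (-1.74, SE 0.29, adjusted p = 0.0444) and TET5 (-1.17, SE 0.18, adjusted p = 0.0258) lower. AT2G34655 was at 3.70 ± 0.45 in root MS, below its 4.05 ± 0.11 in J0571 DEX, so a fall in root tips had little room to show. On all root arrays AT1G28160 lay at 3.27 to 4.40, below the array medians and not shown to exceed background. Its change in root tips, with or without CHX, may thus be understated. AT4G38650, at 1.66 (SE 0.28), missed the threshold (adjusted p = 0.0501) and passed without root DEX replicate 1 (0.0186) or root MS replicate 3 (0.0489). It also passed with array medians equal (0.0304), the lowest features left out (0.0341), the trend and robust options (0.0374), array weights (0.0392), the replicate block (0.0224), identical features once (0.0381) or only features of 1 named gene (0.0303). In total 20 features passed, 17 higher and 3 lower in J0571, and 20 higher and 1 lower with array medians equal. Without J0571 DEX replicate 1 it was 19 higher and 10 lower, and without root DEX replicate 1 it was 16 higher and 9 lower.

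The count of 20 was 12 without root MS replicate 1, 13 without root MS replicate 2, 12 without J0571 control replicate 2, and 11 without root DEX replicate 2, root DEX replicate 3, J0571 control replicate 1 or J0571 DEX replicate 2, each with 1 lower. AT2G38380 passed in all 12 fits that left out 1 array, and AT1G28160 in all but those without root MS replicate 1 (0.0537) and J0571 DEX replicate 2 (0.0608). AT1G23205 passed only without root DEX replicate 1, J0571 control replicate 3 or J0571 DEX replicate 1 (0.0575 to 0.110 in the other 9). TET5 passed only without root DEX replicate 1, root MS replicate 3, J0571 DEX replicate 1 or J0571 DEX replicate 3 (0.0578 to 0.110 in the other 8). AT2G34655 passed only without root DEX replicate 1 or root MS replicate 3 (0.0896 to 0.132 in the other 10), and AT3G17130 only without J0571 control replicate 3 or J0571 DEX replicate 1 (0.0505 to 0.110). Other settings also ended calls: TET5 with quantile normalization (0.0578), array medians equal (0.0820) or array weights (0.0515), AT2G34655 with array medians equal (0.0820) or the trend and robust options (0.0508), and AT1G23205 with the latter (0.0880). The replicate block ended those of AT3G17130 (0.111) and AT2G34655 (0.114). Of the lists, the TMO5 and LHW family was lower in J0571 (median -0.29, adjusted p = 0.0499), a call lost with an estimated correlation (adjusted p = 0.405), quantile normalization (0.0755) or the replicate block (0.0554). The others had adjusted p of 0.208 to 0.811, with ground tissue markers at a median of 0.05, a mean of -0.04 and a test pointing down.

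Against the response in root DEX+CHX, AT1G28160 (2.17, SE 0.30, adjusted p = 0.00844) and AT4G38650 (2.13, SE 0.28, adjusted p = 0.00604) were higher in J0571 cells, as were AT3G17130 (1.84, SE 0.27, adjusted p = 0.0173) and AT5G47900 (0.98, SE 0.15, adjusted p = 0.0247). Lower in J0571 were AT2G38380 (-1.34, SE 0.17, adjusted p = 0.00538) and TET5 (-1.10, SE 0.18, adjusted p = 0.0431). The early auxin response list was lower in J0571, with all 8 members below 0 (median -0.62, adjusted p = 7.81e-07, and 0.00106 with an estimated correlation), and 3 members passed over the list alone. In this comparison CHX was present in the root groups and not in the J0571 groups. Against root DEX, without CHX, the early auxin response list did not pass (median -0.14, camera adjusted p = 0.338). Against root DEX+CHX 17 features passed in all, 15 higher and 2 lower. AT3G17130 passed only without root CHX replicate 3, root DEX+CHX replicate 3, J0571 control replicate 3 or J0571 DEX replicate 1 (0.0508 to 0.0806 in the other 8). AT5G47900 passed only without root CHX replicate 2, root CHX replicate 3, J0571 DEX replicate 1 or J0571 DEX replicate 3 (0.0556 to 0.102 in the other 8), and TET5 only without root DEX+CHX replicate 1 or root CHX replicate 2 (0.0542 to 0.190). TET5 was also lost with quantile normalization or array medians equal (0.115 each), AT3G17130 with quantile normalization (0.0553) and AT5G47900 with the trend and robust options (0.145). With the replicate block AT3G17130 (0.0560), TET5 (0.0503) and AT5G47900 (0.0773) were lost. The TMO5 and LHW family had an adjusted p of 0.0591, or 0.0416 with array medians equal, with 1 member lower over the list alone, and the others 0.468 to 0.918, with ground tissue markers at a median of 0.04, a mean of -0.03 and a test pointing down.

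Cycloheximide alone is the background of the CHX groups, and root CHX was compared with root MS to describe it. AT3G29000, an EF-hand calcium-binding protein, rose from 2.97 ± 0.24 to 9.53 ± 0.05 (log2 change 6.56, SE 0.14, adjusted p = 1.72e-09), and AT1G30190 from 3.14 ± 0.13 to 9.62 ± 0.14 (6.48, SE 0.12). Next came AT1G35210 (6.25), AT5G22520 (6.06), AT1G07135 (5.95), the flotillin-like AT5G64870 (5.94), AT1G06135 (5.93), AT5G40000 (5.89), AT2G32200 (5.85), AT5G11140 (5.81), AT1G72920, with a TIR domain (5.75), and AT1G51913 (5.73). These 12 genes lay at 2.44 to 4.58 in root MS, below the array medians and not shown to exceed background, so the changes are at best lower bounds and their order is not settled. The largest falls were in AT2G43890, a pectin lyase-like protein, from 6.92 ± 0.33 to 3.61 ± 0.94 (-3.31, SE 0.47, adjusted p = 0.000434), and AT4G03292 (-3.07, SE 0.16), then AT2G41810 (-2.52), AT3G46190 (-2.48), AT5G41280 (-2.25), AT1G05650 (-2.21), AT4G24410 (-2.13) and AT1G44030 (-2.11). AT2G43890 ended within the range just called not shown to exceed background. Its fall is thus at best a lower bound, and the order of the falls is not settled. STZ (ZAT10), the 1 early stress gene named here, rose by 3.13 (SE 0.29, adjusted p = 2.18e-05).

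Among the fixed lists the early auxin response genes rose most clearly with CHX: 6 of 8 rose over all features and over the list alone, with a median of 1.57 (adjusted p = 7.27e-06, and 0.00761 with an estimated correlation). GH3.1 rose by 3.92 (SE 0.26), GH3.3 by 3.75 (SE 0.34), the lateral root factors LBD29 by 3.24 (SE 0.15) and LBD16 by 1.85 (SE 0.10), IAA29 by 1.29 and WES1 by 1.01, while IAA30 stood at 0.23 and IAA20 at -0.26. Both vascular Dof factors named here rose, AT5G02460 (PEAR2) by 1.47 (SE 0.13) and DOF2.1 by 0.91 (SE 0.14), with an adjusted p of 0.0117 for the list and 0.0692 with an estimated correlation. In the TMO5 and LHW family AT3G56770 (bHLH107) rose by 0.97 (SE 0.13) and AT2G41130 (bHLH106) by 0.83 (SE 0.18), and LHW was at -0.18 (adjusted p = 0.189; -0.28 and 0.0481 without root MS replicate 1). The list had an adjusted p of 0.166.

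Of the SAC51 family AT5G09460 rose by 0.76 (SE 0.15), and AT5G50010, at 0.35 (SE 0.12, adjusted p = 0.0540), passed over the list alone and without root CHX replicate 1 (0.0283) or under either scaling (0.0490 quantile-normalized, 0.0146 with array medians equal). AT5G50010 also passed with the lowest features left out (0.0369), the trend and robust options (0.0321), the replicate block (0.0315) or only features of 1 named gene (0.0499). The list did not pass (adjusted p = 0.132). The cytokinin-induced type-A response regulator RR16 rose by 1.29 (SE 0.40, adjusted p = 0.0339), a call lost without root CHX replicate 1 (0.123), root MS replicate 2 (0.0811), root CHX replicate 2 (0.0659) or root MS replicate 3 (0.106). ARR15, at 0.76 (SE 0.30, adjusted p = 0.0786), passed over that list alone and under either scaling (0.0144 and 0.0365); the list had an adjusted p of 0.166. Of 4 ground tissue markers AT5G41920 (SCL23) rose by 0.38 (SE 0.11, adjusted p = 0.0193), a call lost without root CHX replicate 1 (0.0505), root MS replicate 2 (0.0704), root MS replicate 3 (0.0622) or root CHX replicate 3 (0.0563), with the trend and robust options (0.0564) or with only the 6 arrays (0.0671). Its list had an adjusted p of 0.510, and JKD was at -0.14 (SE 0.10). No member passed in the polyamine list, where AT5G15950 was at 0.47 (adjusted p = 0.0727; 0.00997 without root MS replicate 1, 0.0249 with array medians equal, 0.0478 with array weights) and AT3G25570 at -0.50, with 1 higher and 1 lower over the list alone, an adjusted p of 0.747 and a median of -0.15, which is 0.02 with array medians equal. Nor did the root hair expansins EXPA7 at -0.51 (SE 0.19), lower over the list alone, and EXPA18 at -0.41 (list adjusted p = 0.304), or PHV (-0.32), OPS (-0.30) and RCA (-0.17). EXPA7 passed in the fit over all 18 arrays (0.0404) or over only the 6 arrays (0.0194), and PHV with quantile normalization (0.0489), the lowest features left out (0.0494) or array weights (0.0413).

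With CHX 11546 features passed, 3988 risen and 7558 fallen, and the median change of all features was -0.13. That median was 0.14 higher under quantile normalization, with 5620 risen and 5821 fallen, and 0.17 higher with array medians equal, with 5906 risen and 3742 fallen. Of the 4553 called features that carry a gene name, 2315 rose and 2238 fell, and 926 rose and 85 fell at least 2-fold; unnamed features present in several identical copies made up 2824 of the falls and 6 of the rises. With identical features counted once 3982 rose and 5274 fell. Of 148 genes with several features, 2 had opposite calls and 49 had calls on some features only.

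The sorted cells were compared with whole root tips only to describe them by marker genes, since background, time, protoplasting and sorting all differ. Of the ground tissue markers, 3 were higher in J0571 control than in root MS: the zinc-finger factor JKD by 0.87 (SE 0.11), the cortex marker AT1G62500 (CO2) by 0.73 (SE 0.13) and AT3G45260 (BIB) by 0.58 (SE 0.16), with adjusted p of 9.63e-06, 0.000255 and 0.00678. AT5G41920 (SCL23) was at 0.12 (SE 0.11), or 0.36 with array medians equal, where it passed, and the list did not pass (adjusted p = 0.252). The root hair expansins were lower, EXPA7 by -2.50 (SE 0.18) and EXPA18 by -2.27 (SE 0.26), with an adjusted p of 0.0394 for the list and 0.476 with an estimated correlation. PHV, a vascular HD-ZIP III factor, was lower by -1.30 (SE 0.12), STZ higher by 1.09 (SE 0.26), the phloem gene OPS at 0.14 (SE 0.22) and RCA, Rubisco activase, at -0.05 (SE 0.51).

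**Figure D4:**
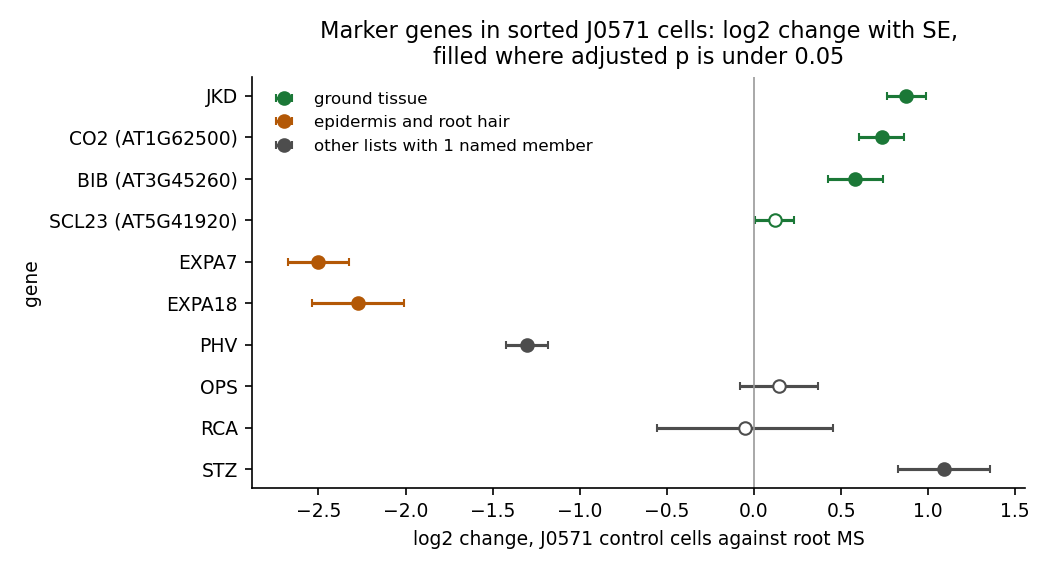
Log2 change of marker genes (y axis) between J0571 control cells and root MS (x axis, with SE), filled where the adjusted p is under 0.05. JKD, CO2 and BIB lay above 0 by 0.58 to 0.87, EXPA7 and EXPA18 below -2.2.

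Of the auxin list GH3.3 (1.63, SE 0.30), GH3.1 (1.08, SE 0.25), IAA29 (0.58) and WES1 (0.50) were higher in J0571 control and LBD29 lower (-1.56, SE 0.18), with an adjusted p of 0.598 for the list. LHW was higher by 0.52 (SE 0.09) and AT3G56770 by 0.57 (SE 0.20; list adjusted p = 0.582). The SAC51 members AT5G50010 (-0.998, SE 0.21) and AT5G09460 (-0.62, SE 0.20) were lower (list adjusted p = 0.252). Of the S-adenosylmethionine decarboxylases of the polyamine list, AT3G25570 was lower by -1.84 (SE 0.19), AT5G15950 higher by 0.80 (SE 0.19) and SAMDC at -0.02, or 0.22 with array medians equal, where it passed. ARR15 was higher (0.75) and RR16 lower (-0.92), and the Dof factors AT5G02460 (-0.13) and AT2G28510 (-0.16) did not pass. The medians of the type-A regulators (-0.09 as deposited, 0.07 quantile-normalized, 0.16 with array medians equal), the Dof factors (-0.14, -0.10 and 0.10) and the polyamine list (-0.02, -0.13 and 0.22) changed sign with the scaling; their adjusted p were 0.810, 0.598 and 0.598.

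Some of these calls rested on 1 array or on the setting. WES1 was lost without root MS replicate 3 or J0571 control replicate 3 (adjusted p = 0.123 and 0.129), and IAA29 without root MS replicate 2, root MS replicate 3, J0571 control replicate 2 or J0571 control replicate 3 (0.0899 to 0.135). ARR15 was lost without root MS replicate 1, root MS replicate 3, J0571 control replicate 1 or J0571 control replicate 2 (0.0660 to 0.177), and RR16 in each fit but that without root MS replicate 3 (0.0561 to 0.168). AT5G09460 was lost without root MS replicate 2, root MS replicate 3 or J0571 control replicate 1 (0.0589 to 0.108), and AT3G56770 without root MS replicate 1, root MS replicate 2, J0571 control replicate 1 or J0571 control replicate 3 (0.0597 to 0.145). IAA30, at 0.52, was gained without root MS replicate 3 (0.0429) or J0571 control replicate 3 (0.0484). With array medians equal AT5G09460 (0.130) and RR16 (0.111) were lost and LBD16 (0.00510), IAA30 (0.0208) and IAA20 (0.0274) gained, and with array weights RR16 (0.0935) and AT3G56770 (0.137) were lost. Between these groups 18782 features passed, 10187 higher and 8595 lower in J0571 control, with a median change of 0.05. With array medians equal that median moved up by 0.24, and 16024 were higher and 6313 lower. Of the camera results given here, those of the early auxin response list for CHX, DEX with CHX, their interaction and J0571 against root DEX+CHX, and of the SAC51 family in both root DEX contrasts, held with an estimated correlation, and the others did not. For the results that held, that estimate was below 0. It was -0.031 or -0.020 for the early auxin list and -0.16 for the SAC51 family. In these cases the setting thus did not allow for more correlation than the preset 0.01. Some results that were lost also had an estimate below 0. It was -0.24 for the Dof factors with CHX and -0.026 for the early auxin list in J0571 DEX. Those calls were thus not lost to a higher correlation.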

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

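In this part, the splits of the arrays for the early auxin response list, the slope over other genes, the test without IAA29 and the division of the splits by the grouping of the J0571 arrays were chosen after the result was seen.

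The early auxin response genes were higher with DEX in the presence of CHX, and the response to DEX differed with CHX for this list (adjusted p = 1.21e-05, and 0.00867 with an estimated correlation). An uneven split of the arrays could give this. Of 100 splits, 1, the real one, reached a camera p with an estimated correlation as small as the real 0.00108, and the smallest in the others was 0.00476. The splits were run for this list alone, picked from 8 after its result was seen, and do not allow for that choice. A stronger effect of CHX in the root DEX+CHX arrays could also raise these genes, as 6 of the 8 rose with CHX. This was checked in root DEX+CHX against root CHX and not in the interaction. There the slope over 16500 other genes gives 28.7% of the list's mean shift (0.0943 of 0.328). This argues against a CHX effect stronger by the same proportion in all genes as the whole cause of that shift. Of the 8 members, 7 lay above the value the slope gives. Genes with a similar rise with CHX were not compared as a set. A stronger CHX effect on such genes alone thus stays open. In the same contrast IAA29 alone does not make the shift, since the other 7 members had a mean of 0.25 and a camera p of 0.00501 with an estimated correlation. The interaction was not tested without IAA29.

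The responses to DEX differed between J0571 cells and root tips in 20 features against root DEX and 17 against root DEX+CHX. Against root DEX the differences were 2.103 for AT1G28160, 1.19 for AT1G23205, 1.70 for AT3G17130, -1.74 for AT2G34655, -1.27 for AT2G38380 and -1.17 for TET5, and the TMO5 and LHW family list had an adjusted p of 0.0499, and 0.405 with an estimated correlation. Against root DEX+CHX they were 2.17 for AT1G28160, 2.13 for AT4G38650, 1.84 for AT3G17130, 0.98 for AT5G47900, -1.34 for AT2G38380 and -1.10 for TET5, and the early auxin response list had an adjusted p of 7.81e-07, and 0.00106 with an estimated correlation. CHX was present in the root DEX+CHX and root CHX groups but not in the J0571 groups. Against root DEX, without CHX, the early auxin response list did not pass (median -0.14, camera adjusted p = 0.338). Of 100 splits of the arrays, 10 gave at least 20 features (at most 42) and 9 gave at least 17 (at most 35). Of these, 8 and 9 kept the grouping of the J0571 arrays into control and DEX and so carry its calls, which is why these splits do not decide whether chance can be excluded. Among the 90 splits that did not keep it, 2 gave at least 20 features (at most 23) and 0 gave at least 17 (at most 9). With the J0571 grouping kept and the root arrays in other groups, the counts were 19 to 42 and 16 to 31, so counts near 20 and 17 also arose with other groupings of the root arrays.

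Splits within the other comparisons say less. For root DEX against root MS and for root DEX+CHX against root CHX, 10 of 10 splits had at least the real count of 0, with at most 16 and 0 in the others; for root CHX against root MS (real 11546, highest other 0), J0571 DEX (real 13, highest other 0) and J0571 control against root MS (real 18782, highest other 10) only 1 of 10 did, the real one. With 10 splits no share under 0.05 can arise. For the interaction 100 of 100 splits had at least the real count of 0, with up to 30 features. Where the real count is 0 every split must reach it, so these splits say nothing about chance.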

How the results depend on the processing

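The alternatives with identical features counted once, with only features of 1 named gene and for the overlaps beyond the 200 of smallest p were chosen after the data were seen. The cause of a changed result was not tested unless stated. For arrays, signal over background limits what a result can show, and leaving out the lowest 30% of features changed no count by more than 1.5-fold.

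For root DEX against root MS, the fit over all 18 arrays called 1 feature and each other alternative 0, except that leaving out 1 array gave 0 to 15, the 15 without root DEX replicate 1. For root DEX+CHX against root CHX and for the interaction all alternatives gave 0. For root CHX against root MS a 1.5-fold minimum left 6743 of 11546 calls (2726 risen, 4017 fallen), as it must leave fewer, and testing only features of 1 named gene gave 4412 (2291 risen, 2121 fallen), as fewer were tested. Leaving out 1 array gave 8873 to 10307.

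For J0571 DEX against J0571 control the fit over all 18 arrays gave 68 features, which held all 13, and only features of 1 named gene gave 3. Leaving out 1 array gave 5 to 9. The replicate block gave 0, with 2978 features at an unadjusted p under 0.05. With it AT4G38650 had an adjusted p of 0.137, AT1G28160 0.185 and AT2G34655 0.280. The replicate block gave 19 instead of 20 features for the response difference against root DEX (16 shared) and 21 instead of 17 against root DEX+CHX (13 shared). Against root DEX it ended the calls of AT3G17130 (adjusted p = 0.111), AT2G34655 (0.114) and the TMO5 and LHW family (0.0554), while the SAC51 family (0.0395) and AT4G38650 (0.0224) passed. Against root DEX+CHX it ended those of AT3G17130 (0.0560), TET5 (0.0503) and AT5G47900 (0.0773). No label says whether arrays with the same number were handled together. Deviations from the group means of such arrays correlated with r from -0.243 to 0.197 in 18 root pairs (3 over 0.1). In 3 J0571 pairs r was from 0.0176 to 0.254 (2 over 0.1), so a pairing of the J0571 arrays is not excluded.

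For the response difference against root DEX only features of 1 named gene gave 8 instead of 20, and leaving out 1 array 11 to 29. Against root DEX+CHX they gave 6 instead of 17, and 13 to 16. For J0571 control against root MS only features of 1 named gene gave 8427 instead of 18782, and leaving out 1 array 17001 to 17728. There SAMDC, at -0.02, became 0.22 (adjusted p = 0.0437) with array medians equal, which moves all features of this contrast up.

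The overlap of DEX calls was 0 for each pair, as the root contrasts had no calls. Taking the 200 features of smallest p gave 12 for root DEX and root DEX+CHX, 8 for root DEX and J0571 DEX and 7 for root DEX+CHX and J0571 DEX, and 20, 11 and 8 with identical features once. With each contrast fitted on only its own 6 arrays the last counts were 15, 12 and 9.

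For the 64 list results, an estimated correlation and the replicate block gave 128 values. Of these 121 were unchanged, 6 lost the call and 1 gained it. Most lists had no call to lose, and those that stayed without one count as unchanged. An estimated correlation ended the calls of the Dof factors with CHX, the early auxin list in J0571 DEX and the epidermis and root hair markers in J0571 control. It also ended those of the TMO5 and LHW family in J0571 DEX and against root DEX. Quantile normalization and equal array medians gave another 128, of which 126 were unchanged in this sense. The TMO5 and LHW family lost the call against root DEX with quantile normalization (0.0755). It gained the call against root DEX+CHX with array medians equal (0.0416). Of 3343 values for the 309 gene results, 3249 were unchanged, 61 lost the call, 32 gained it and 1 reversed sign. Genes that stayed without a call count as unchanged here too. The fits of a gene that left out 1 array entered only as their lowest and highest change. Each was judged by the largest adjusted p among these fits. Losses in several such fits were thus not counted singly, and a gain in only some of them was not counted.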

Other observations

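In this part, the tests of families, the splits of the arrays for overlaps, the overlaps in opposite directions, the counts with identical features once and the set of J0571 features in root tips were chosen after the result was seen.

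Between root CHX and root MS, 47 sets of genes that share a symbol stem or are encoded in the plastid were also compared. Only some are given here, picked after their results were seen. A set holds only genes whose feature carries such a name here, so it need not cover the whole family. Of 10 plant U-box ubiquitin ligases (PUB) 8 rose with CHX, 8 with quantile normalization and 9 with array medians equal (median 1.5), among them PUB54 by 2.47 (SE 0.22) and PUB23 by 1.85 (SE 0.13). Of 6 calmodulin-like genes (CML) 4 rose, 4 under either scaling, led by CML37 at 4.79 (SE 0.14), CML23 at 3.87 and CML38 at 3.45, and of 7 WRKY transcription factors 5 rose, 5 under either scaling, led by WRKY41 at 5.56 (SE 0.51). Of 63 genes encoded in the plastid 58 fell (median -0.55), 52 with quantile normalization and 42 with array medians equal, among them rbcL, the large subunit of Rubisco, by 0.66 (SE 0.08) and ndhC, a subunit of the NDH complex, by 1.30 (SE 0.10). Adjusted p were 2.24e-07, 0.00337, 0.00685 and 2.10e-22, and 0.0662, 0.135, 0.135 and 0.247 with an estimated correlation.

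The same 47 sets were compared between J0571 control cells and root MS, and again only some are given. Of 17 IQ-domain genes (IQD) 12 were higher in J0571 control, 12 and 14 under the 2 scalings (median 0.68), with IQD22 at 2.19 (SE 0.12), IQD19 at 2.01 and IQD18 at 1.81. Of 8 autophagy genes (ATG) 7 were lower, 7 and 6 under the scalings (median -0.64), with ATG8E at -1.69 (SE 0.11) and ATG8F at -1.57, and of 14 SWEET sugar transporters 7 were lower under each scaling (median -0.63), with SWEET2 at -3.33 (SE 0.16) and SWEET16 at -2.78. Adjusted p were 0.00355, 0.00355 and 0.0118, and 0.0600, 0.0600 and 0.0941 with an estimated correlation.

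Among the 200 features higher with DEX of smallest unadjusted p, the DEX contrasts shared more than independent lists would, AT4G38650 and AT3G23880 among all 3, though no feature passed in either root contrast. Of 100 pairs of splits of the arrays, 1, the real one, shared at least the real 20 features between root DEX and root DEX+CHX, against at most 4 in the others. For root DEX and J0571 DEX 2 of 100 reached the real 11, and for root DEX+CHX and J0571 DEX 2 reached the real 8, in each case with a highest other equal to the real value. Features of small spread might rank high in both root contrasts whatever their direction, but the larger overlap in opposite directions was 5. A response to DEX without TMO5-GR may underlie part of the overlap and stays open, as 0 arrays had DEX without the construct.

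More features fell than rose with CHX in the values as deposited (65.5% of calls), but 50.9% fell with quantile normalization and 38.8% with array medians equal, where more rose. Counting identical features several times could inflate the falls, but with each set counted once 57.0% of the calls still fell (52.1% to 56.0% without 1 array), which argues against it as the whole cause. The scaling of the arrays may shift all features, and the median change as deposited was -0.133. As the direction turns with the scaling and no outside standard was used here, this stays open.

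The 9 distinct features that rose in J0571 cells were also looked at as a set in root tips, where 7 were higher with DEX (mean 0.23; camera p = 0.00659, and 0.0224 with an estimated correlation). Without AT4G38650 it was 6 of 8 (mean 0.06), and with CHX present 3 of 9 (mean 0.09), and camera found no shift in either case.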
